A study of Mus musculus with 3 samples.

How the data were processed

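Messenger RNA was measured in 3 libraries of mouse vestibular cells described by the labels as resembling black balls. The labels call the cells wild-type macrophages from the vestibule, the balance organ of the inner ear, while the series title speaks of melanocytes, the pigment cells. Per the labels' protocols, 18 such cells came from 9 mice, with 3 mice per group, and polyadenylated RNA was copied from oligo(dT) primers with the SMART-Seq HT kit, amplified by PCR, made into libraries with the KAPA Hyper Prep kit and sequenced on an Illumina NovaSeq instrument. How the 18 cells were divided among the 3 libraries is not given in the sources used here. The labels give 1 group and no control group, so every comparison below is between gene lists within the same libraries. The libraries are treated as 3 replicates, and because the labels do not tie each library to named animals, p-values measure only the spread between these libraries, which may be technical.

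The deposited table holds raw counts per gene and FPKM, a value scaled by gene length and library total, for each library, per the file headers. The submitters' processing notes name HISAT2, a spliced aligner, StringTie, a transcript assembler, edgeR and the mouse build GRCm39, without versions, roles or order. The deposited FPKM values equalled the count divided by a fixed length per gene and by the column's total count. The length implied by count and FPKM differed between libraries by at most 0.0528%. No gene was 0 in one measure and above 0 in the other. The implied length had a median of 4887 bp over genes with a count in every library. It was not compared with transcript lengths, so TPM may be too low or too high for genes where it departs from them. For Gapdh the implied length was longer than the span of the gene itself. CPM does not use this length. The table lists 57180 genes, of which 525 have no symbol. Those genes carry Ensembl identifiers, were kept, and took 0.173% ± 0.0255 of the counts (SD, n = 3). How reads matching several genes were assigned, and whether strand was used, is not given in the sources used here. Genes with near-identical copies (the globins, ferritin light chain, ubiquitin, calmodulin, ribosomal protein genes and their pseudogenes) and genes that overlap others therefore have uncertain levels.

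The total count was 18460546 in replicate 1, 15086854 in replicate 2 and 14095521 in replicate 3. A floor of 3 counts corresponds to 0.163, 0.199 and 0.213 CPM (counts scaled by the library total alone) in replicates 1 to 3. PCR copies were not marked by molecular identifiers, so this floor covers counting error only. With few cells behind each library, amplification from small amounts of RNA adds spread that sequencing depth does not reduce.

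Because genes are compared with genes within a library, FPKM was rescaled to the same total in each library (TPM, the transcript-based unit scaled by gene length first) and analysed as log2(TPM + 1), which compresses low values. A gene was called above 1 TPM by limma's moderated test of its mean over the 3 libraries against log2(1 + 1), in an intercept-only model with a mean-variance trend, one-sided, with Benjamini-Hochberg adjustment over the 27265 genes with a count in at least 1 library and a threshold of 0.05. Counts for each list are given over all genes tested and, where that differs, adjusted over the list alone. The level of a list is the mean of log2(TPM + 1) over its genes in each library, given as mean ± SD over 3 libraries, beside its percentile among 10000 random lists of the same size drawn from all genes tested. That percentile describes these libraries, since genes are not replicates. The level of the macrophage list minus that of each of the 18 other cell type lists was tested by an exact sign-flip permutation test over libraries, two-sided, with Benjamini-Hochberg adjustment over the 18 comparisons. With 3 libraries the smallest p this test allows is 0.25, so it cannot reach 0.05. Agreement between libraries is given as Pearson and Spearman correlation across genes, and as the common biological coefficient of variation that edgeR estimates from the counts.

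The gene lists, tests and rule for named genes were fixed before the data were examined. There are 19 lists of cell type markers, 13 of functions and 3 for reference (housekeeping, mitochondrially encoded, and Y-linked genes with Xist), and no gene stands in more than 1 of them. The text names the 20 genes with the highest mean TPM (without mitochondrially encoded genes, genes with symbols starting Rpl or Rps, ribosomal RNA genes and annotated pseudogenes), all genes of the macrophage and melanocyte lists with values for at most 12 of each, the 4 members with the highest TPM in each other list, the 10 genes with the largest SD between libraries among those with a mean of at least 10 TPM, and a fixed set of single genes. A few others are named as chosen after their values were seen, and a few genes of the lists count in the list results but are not reported here by name. Coordinates are those of the deposited table (GRCm39, 1-based). The reference annotation used here, GENCODE M21, is on the older build GRCm38 and served only for counting 50-base sequences shared between transcripts.

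The test was tried on simulated data, with 200 genes set at each of several true levels among 25898 genes in the fit. It called 0% of genes at a true level of 1 TPM, 0.5% at 2 TPM, 7.5% at 4 TPM, 45.5% at 8 TPM and 80% at 16 TPM. The simulation gave every gene the same common coefficient of variation, and the measured libraries gave more calls from 3 TPM up: 0% of the 3434 genes with a mean of 1.5 to 3 TPM passed, 39.9% of the 2426 genes at 3 to 5 TPM and 90% of the 2265 genes at 6 to 10 TPM. In the same simulation a coefficient of variation of 0.937 was recovered as 0.929. Alternatives were pseudocounts of 0.1 and 5, CPM without gene length, totals without mitochondrially encoded genes, edgeR's TMM factors, genes counted in all 3 libraries, leaving out each library, the median in place of the mean, a level of 10 TPM, limma without the trend, a shorter melanocyte list and the pan-leukocyte list in place of the macrophage list. In CPM the test was against 1 CPM, a different bar from 1 TPM, and 11827 genes passed, against 10264 in TPM. Random lists from protein-coding genes alone were added after seeing the data. Analyses ran in R 4.3.3 with limma 3.58.1 and edgeR 4.0.16, and in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The count column and the FPKM column of each labelled sample were found by the sample's description.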

Results

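The study profiled the transcripts of cells of the mouse vestibule that resembled black balls, in 3 libraries of 1 group. Each library held between 14095521 and 18460546 counts. Replicates 1, 2 and 3 had a count for 22376, 22333 and 22094 genes, and 16674, 15799 and 16203 genes stood at 1 TPM or more. Protein-coding genes took 91.2% ± 0.772 of the counts (SD, n = 3, as for all values below unless stated), annotated pseudogenes 6.58% ± 0.451 and mitochondrially encoded genes 3.47% ± 1.67. The 3 libraries shared 12720 genes at 1 TPM or more. In limma's test 10264 of 27265 genes stood above 1 TPM, among them 8194 of 16219 protein-coding genes and 1386 of 4588 pseudogenes, and 11428 genes had an unadjusted p under 0.05.

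The 20 most abundant genes included 3 globin genes and 3 genes of inner ear proteins. Ptgds, a prostaglandin D synthase that is secreted (chromosome 2, 25356721 to 25360058), was highest at 28330 ± 6104 TPM and alone took 2.47%, 3.18% and 4.36% of the counts in replicates 1, 2 and 3. Hba-a1, an alpha globin, stood at 16714 ± 7461 TPM and Hbb-bt, a beta globin, at 10492 ± 4500 TPM, with the second alpha globin gene Hba-a2 at 4279 ± 2174 TPM. Coch, which encodes cochlin, an extracellular matrix protein of the inner ear (chromosome 12, 51640124 to 51652554), stood at 8005 ± 2950 TPM. Otor, encoding otoraplin, stood at 3662 ± 1014 TPM and Otos, encoding otospiralin, at 3433 ± 1074 TPM. The calcium-binding S100a1 and S100b stood at 8315 ± 901 and 8131 ± 1378 TPM, the lipocalin Apod at 8433 ± 1586 TPM and the secreted phosphoprotein Spp1 at 4731 ± 2650 TPM. Lyz2, the lysozyme of myeloid cells, was the macrophage marker among these 20 genes, at 4616 ± 1632 TPM. The others were Ftl1-ps1 (12118 ± 1595 TPM), Ubb (7022 ± 2066), Calm2 (4804 ± 2365), Skp1 (4178 ± 1912), Gm26377 (3883 ± 1507), B2m (3335 ± 998), the interferon-inducible Ifi27l2a (3087 ± 1439) and Selenow (3040 ± 495). Each of the 20 passed limma's test against 1 TPM, with adjusted p between 1.3e-05 and 3.17e-05. The Ftl1-ps1, Ubb, Calm2 and globin values are uncertain because near-identical copies exist, and Gm26377 (chromosome 9, 78385810 to 78385917) lies within Eef1a1 (78385731 to 78396433).

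The labels call the cells macrophages and the title speaks of melanocytes, so the first comparison set the markers of these cell types side by side in each library. Both sets of transcripts were present, and the macrophage list stood higher. Of the 18 macrophage markers, 15 stood above 1 TPM, and of the 15 melanocyte markers, 9 did. The macrophage list had a mean level of 5.34 ± 0.19 and the melanocyte list one of 3.46 ± 0.10 on the log2(TPM + 1) scale. The difference was 1.88 ± 0.19, with values of 1.82, 1.73 and 2.09 in replicates 1, 2 and 3. The macrophage list was higher in 3 of 3 libraries (exact sign-flip permutation test, two-sided, p = 0.25, the smallest that 3 libraries allow, adjusted p = 0.265 over 18 comparisons). The difference depended on gene length and on the list chosen: it was 1.11 in CPM without length, and 0.39 with the pan-leukocyte list in place of the macrophage list. The lists hold different genes, so their levels do not measure how much RNA each cell type gave.

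The macrophage markers with the highest levels were Lyz2, Ctss, C1qb and Tyrobp. After Lyz2 (chromosome 10, 117113236 to 117118226) came the lysosomal protease Ctss (chromosome 3, 95434097 to 95463714) at 907 ± 294 TPM. The 3 chains of complement C1q, encoded side by side on chromosome 4, stood at 563 ± 125 TPM for C1qb (136607440 to 136613498), 229 ± 153 TPM for C1qa (136623228 to 136626114) and 142 ± 46.0 TPM for C1qc (136617115 to 136620376). The signalling adaptors Tyrobp and Fcer1g stood at 248 ± 79.5 and 174 ± 46.6 TPM. The lysosomal glycoprotein Cd68 (chromosome 11, 69555039 to 69556979) varied little, at 152 ± 6.46 TPM. Aif1, the endotoxin co-receptor Cd14, Mertk and the CSF1 receptor Csf1r (chromosome 18, 61233670 to 61265221) were lower, at 24.3 ± 10.8, 23.6 ± 4.37, 12.3 ± 3.88 and 12.9 ± 6.55 TPM. Mrc1, Fcgr1 and Adgre1, the gene of the F4/80 antigen (chromosome 17, 57665691 to 57790527, 6.88 ± 4.64 TPM), also passed the test. The call for Fcgr1 ended with a pseudocount of 5, without replicate 1 (limma, adjusted p = 0.107) and without replicate 2 (adjusted p = 0.0817). Cx3cr1, Itgam and Cd163 did not pass.

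Melanocyte transcripts were led by the pigment enzyme Dct, or dopachrome tautomerase (chromosome 14, 118250202 to 118289656), at 250 ± 19.6 TPM in limma's test against 1 TPM (adjusted p = 1.3e-05). Mlana (chromosome 19, 29675224 to 29686034) stood at 232 ± 33.8 TPM and Pmel, which forms the fibrils of the melanosome (chromosome 10, 128540064 to 128556107), at 72.4 TPM (58.6, 80.3 and 78.3 TPM in replicates 1, 2 and 3). The transporter Slc45a2 (chromosome 15, 11000807 to 11029319) stood at 31.5 ± 1.70 TPM and the transcription factor Sox10 (chromosome 15, 79039108 to 79049440), which glia also express, at 25.2, 17.9 and 31.9 TPM in the same order. Tyr, the rate-limiting enzyme of melanin synthesis (chromosome 7, 87073979 to 87142720), stood at 17.3 ± 13.1 TPM, with 6.83, 32.0 and 13.1 TPM in replicates 1, 2 and 3. Tyrp1, Slc24a5 and Ednrb stood at 11.7 ± 8.29, 10.6 ± 1.93 and 8.93 ± 5.76 TPM. The 6 markers that did not pass were Kit, Gpr143, Trpm1, Oca2, Mc1r and Mitf, the regulator of melanocyte development (chromosome 6, 97784013 to 97998310), at 3.01, 0.817 and 0.492 TPM in replicates 1, 2 and 3. In CPM without gene length, Kit (limma, adjusted p = 0.000208) and Trpm1 (adjusted p = 0.00012) did pass. Kit also passed with a pseudocount of 0.1 (adjusted p = 0.0458), among genes counted in all 3 libraries (0.0288) and without limma's trend (0.0139).

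**Figure D1:**
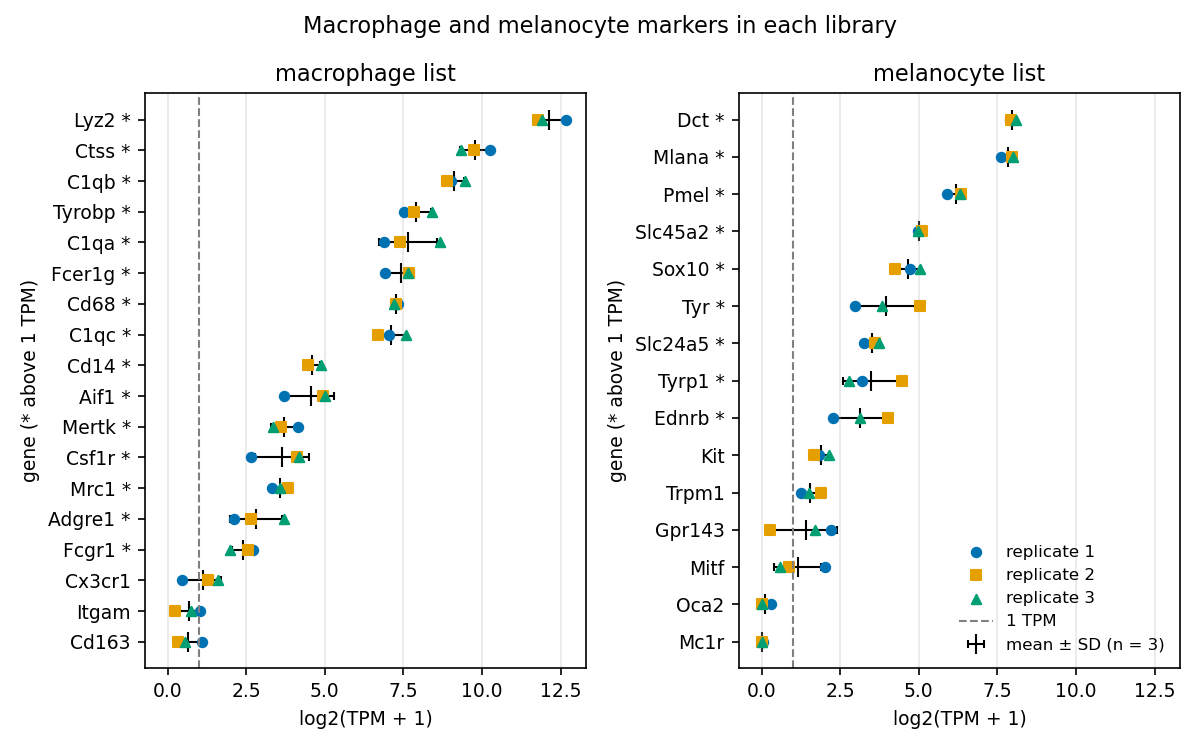
The horizontal axes give log2(TPM + 1) of each macrophage marker (left) and melanocyte marker (right). Points are the 3 libraries, black bars the mean ± SD (n = 3), the dashed line is 1 TPM, and an asterisk marks the 15 macrophage and 9 melanocyte markers above it in limma's test.

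The other cell type lists asked which further cells of the vestibule and the blood left transcripts in the libraries. The macrophage list stood above 15 of the 18 other cell type lists in 3 of 3 libraries, with an exact permutation p of 0.25 and an adjusted p of 0.265 for each. In CPM without gene length the hair cell list stood higher, at a mean level of 5.67 against 5.53. In TPM, the macrophage list was not highest. The macrophage list stood below the erythroid list by a difference of -3.14 ± 0.11 and below the fibroblast list by a difference of -0.59 ± 0.18 in 3 of 3 libraries (exact permutation p = 0.25, adjusted p = 0.265 for both). The inner ear genes Coch (8005 ± 2950 TPM) and Otos (3433 ± 1074 TPM) raised the mean of the fibroblast list, and its order without them was not examined. With medians over list members, the fibroblast list stood at 5.06 and the macrophage list at 4.65. Against the supporting and non-sensory epithelium list the difference of -0.42 ± 0.69 lay within the spread between libraries (exact permutation p = 0.5, adjusted p = 0.5), and the macrophage list was higher in 1 of 3.

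Sensory and epithelial transcripts of the inner ear were among those counted. All 12 hair cell markers passed limma's test against 1 TPM (level 4.65 ± 0.35). The calcium-binding proteins Ocm and Calb2 stood at 155 ± 10.4 and 130 ± 64.7 TPM and the hair cell transcription factor Pou4f3 at 41.6 ± 17.3 TPM. Pvalb stood at 81.1, 96.9 and 438 TPM in replicates 1, 2 and 3, below Ocm in replicates 1 and 2. Gfi1, named after its values were seen, stood at 46.8, 55.4 and 0.622 TPM in the same order, and its call ended with a pseudocount of 5 (limma, adjusted p = 0.0564), without replicate 1 (0.18) and without limma's trend (0.0911). Of the 12 markers of vestibular supporting and non-sensory epithelium, 11 passed (level 5.76 ± 0.51), led by the connexins Gjb6 and Gjb2 (648 ± 166 and 628 ± 159 TPM), Krt18 (449 ± 160 TPM) and Epcam (234 ± 74.6 TPM). The member that did not pass, Tectb, stood at 7.47, 5.88 and 0.352 TPM in replicates 1, 2 and 3, and passed in CPM without gene length (limma, adjusted p = 0.0338) and without replicate 3 (adjusted p = 0.00317). Of the 12 markers in the joint list of vestibular dark cells and strial cells, 10 passed, or 11 adjusted over the list alone (level 4.35 ± 0.28). The list does not tell apart the cell types it joins. Kcnj13 stood at 243 ± 141 TPM, Slc12a2 at 88.9 ± 26.1 TPM, Atp1b2 at 81.7 ± 4.03 TPM and Kcne1 at 80.9 ± 53.9 TPM. The potassium channel gene Kcnj10 (chromosome 1, 172168777 to 172201652) stood at 9.14 ± 1.70 TPM. The fibroblast list (level 5.93 ± 0.06) had 8 of 10 members above 1 TPM, or 9 adjusted over the list alone. After Coch and Otos, which inner ear fibrocytes express, came the proteoglycans Dcn (336 ± 113 TPM) and Lum (108 ± 67.0 TPM). The Schwann cell and glia list (level 4.03 ± 0.59) had 6 of 11 members above, with S100b followed by Pmp22 (88.8 ± 69.1 TPM) and Mal (72.6 ± 13.9 TPM). The neuron list (level 2.97 ± 0.87) had 5 of 10, or 7 adjusted over the list alone, and its 4 most abundant members were highest in replicate 3. In replicates 1, 2 and 3, Snap25 stood at 22.4, 35.2 and 124 TPM, Nefl at 24.9, 23.1 and 69.9 TPM, Tubb3 at 16.2, 1.16 and 64.9 TPM and Nefm at 5.03, 2.66 and 40.6 TPM. The calls for Tubb3 and Nefm ended without replicate 1 (limma, adjusted p = 0.129 and 0.0621), without replicate 3 (adjusted p = 0.0649 and 0.0769), with a pseudocount of 5 and without limma's trend.

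Among blood and vessel lists, the erythroid list was highest (level 8.47 ± 0.27), with 5 of 7 members above 1 TPM, or 6 adjusted over the list alone. These were the 4 globins, with Hbb-bs at 2902 ± 1259 TPM, and Alas2, the first enzyme of heme synthesis in red cells, while Slc4a1 (4.11, 0.112 and 0.484 TPM in replicates 1, 2 and 3) did not pass. Globin counts made up 0.910%, 1.40% and 2.52% of replicates 1, 2 and 3. The pan-leukocyte list (level 3.85 ± 0.33) had 10 of 12 members above, or 11 adjusted over the list alone, led by the NADPH oxidase subunit Cyba (582 ± 267 TPM), Arhgdib (78.0 ± 17.4 TPM), Cd53 (62.8 ± 34.4 TPM) and Cd52 (30.5 ± 22.0 TPM). Ptprc, the gene of the leukocyte antigen CD45 (chromosome 1, 137990599 to 138103446), did not pass at 0.639 ± 0.286 TPM. It did pass in CPM without gene length (limma, adjusted p = 0.0131). The B cell list (level 2.24 ± 0.32) had 2 of 8 members above, Ighm, the mu heavy chain (569 ± 291 TPM), and Cd79a (137 ± 14.4 TPM). Cd79b (9.15, 3.37 and 0 TPM in replicates 1, 2 and 3) did not pass with all libraries and did without replicate 3 (limma, adjusted p = 0.0127). The neutrophil list (level 2.43 ± 1.32) had 3 of 10 above, all highest in replicate 2: S100a8 (6.71, 159 and 61.6 TPM in replicates 1, 2 and 3), S100a9 (6.48, 135 and 57.3 TPM) and Ngp (1.65, 20.3 and 12.6 TPM, not above in CPM without length). Retnlg (1.36, 55.4 and 7.13 TPM) did not pass. Retnlg did pass in limma's test with a pseudocount of 0.1 (adjusted p = 0.0272), among genes counted in all 3 libraries (0.0258), without replicate 1 (0.0163) and without replicate 3 (0.024). The level of this list was 1.17, 3.80 and 2.32 in replicates 1, 2 and 3.

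The remaining cell type lists were low. The osteoclast list (level 1.85 ± 0.32) had 4 of 10 members above, the V-ATPase subunit Atp6v0d2 (50.9 ± 16.4 TPM), the protease Ctsk (29.5 ± 21.5 TPM), Acp5 (7.51 ± 5.07 TPM) and Nfatc1 (4.81 ± 2.61 TPM), and the calls for Acp5 (limma, adjusted p = 0.0603) and Nfatc1 (adjusted p = 0.157) ended without replicate 1. The call for Nfatc1 also ended without replicate 2 (adjusted p = 0.0706) and with a pseudocount of 5. The endothelial list (level 1.47 ± 0.36) had Emcn (7.53 ± 3.27 TPM) and Kdr (6.70 ± 1.97 TPM) above, 2 of 10, while Cldn5 and Esam did not pass with all libraries. Of the alternatives, Cldn5 passed only without replicate 1 (limma, adjusted p = 0.00677) and Esam only without replicate 2 (adjusted p = 0.0173). The list of pericytes and smooth muscle (level 1.26 ± 0.09) had Pdgfrb (8.58 ± 3.63 TPM) and Tagln (9.43, 7.71 and 6.85 TPM in replicates 1, 2 and 3) above, 2 of 10, while Acta2 and Rgs5 did not pass with all libraries. Of the alternatives, Acta2 passed only without replicate 1 (limma, adjusted p = 0.0112). The dendritic cell list (level 0.84 ± 0.35) had 1 of 10 above, Itgax (7.22 ± 3.63 TPM), and the mast cell list (level 0.77 ± 0.21) 1 of 8, Gata2 (10.4 ± 4.04 TPM). The members next in level, Zbtb46, Batf3 and Flt3 of the dendritic cell list and Cma1, Cpa3 and Ms4a2 of the mast cell list, did not pass, except Zbtb46 in CPM without gene length (limma, adjusted p = 0.0048). None of the 10 members of the monocyte list (level 1.38 ± 1.00) and none of the 10 of the T and NK cell list (level 0.63 ± 0.24) passed limma's test over all genes or adjusted over the list alone, and 1 and 0 of them had an unadjusted p under 0.05. The highest monocyte genes were Chil3, Hp, S100a4 and Ly6c2. Chil3 stood at 0.195, 190 and 3.13 TPM and Hp at 0.113, 24.3 and 4.83 TPM in replicates 1, 2 and 3, and the level of the monocyte list was 0.33, 2.31 and 1.502 in the same order. Ly6c2 did pass in limma's test with a pseudocount of 0.1 (adjusted p = 0.0386), in CPM without length (0.0326), among genes counted in all 3 libraries (0.0297) and without the trend (0.0317), and Hp did without replicate 1 (0.0227). The highest T and NK cell genes were Nkg7 (0, 2.96 and 5.76 TPM in replicates 1, 2 and 3), Cd2, Cd4 and Gzma. Among random lists of the same size, the macrophage, erythroid, fibroblast and supporting epithelium lists lay at percentile 100, the melanocyte list at 98.1 and the T and NK cell list at 0.21. Drawn from protein-coding genes alone, random lists put the melanocyte list at percentile 90.5.

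**Figure D2:**
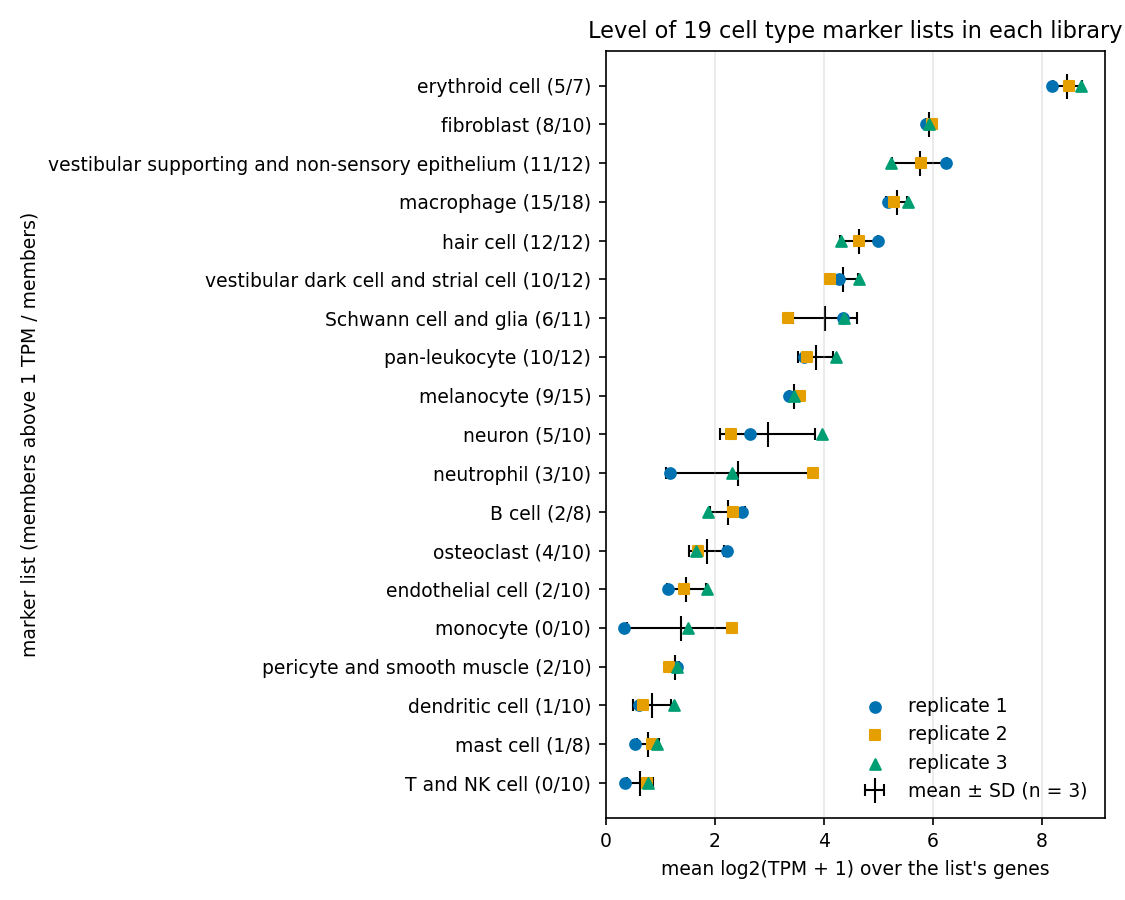
The horizontal axis gives the mean log2(TPM + 1) over the genes of each of 19 cell type lists, and the numbers after each name are the members above 1 TPM in limma's test and all members. Points are the 3 libraries and black bars the mean ± SD (n = 3). The erythroid list is highest at 8.47, the macrophage list stands at 5.34 and the melanocyte list at 3.46.

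The functional lists described the endolysosomal, immune and stress transcripts of the same libraries. All 15 V-ATPase subunits, parts of the proton pump that acidifies lysosomes, stood above 1 TPM (level 6.86 ± 0.19), with Atp6v1g1 at 2184 ± 528 TPM, Atp6v1f at 1060 ± 145 TPM, Atp6ap2 at 223 ± 103 TPM and Atp6v1d at 206 ± 55.8 TPM. All 19 lysosomal genes did (level 5.80 ± 0.29), led by the cathepsins Ctsz (518 ± 187 TPM), Ctsd (497 ± 250 TPM) and Ctsb (411 ± 89.4 TPM) and by Lamp1 (314 ± 115 TPM). All 12 genes of the list for macrophage lipid handling passed (level 5.65 ± 0.06), with Spp1 followed by Apoe (2401 ± 1017 TPM), Cd9 (784 ± 264 TPM) and Lgals3 (149 ± 57.9 TPM). With the median over members in place of the mean, the level of that list was 4.10. Each library is a single sum, so the cells that gave these transcripts cannot be told. Of the 12 iron and heme genes, 11 passed, or 12 adjusted over the list alone (level 5.48 ± 0.11), led by the ferritin chains Fth1 (2341 ± 622 TPM) and Ftl1 (1890 ± 432 TPM), then the stress regulator Nfe2l2 (74.3 ± 29.7 TPM) and the biliverdin reductase Blvra (69.7 ± 7.72 TPM). The list of melanosome and other lysosome-related organelle trafficking (level 3.27 ± 0.21) had 9 of 18 members above, or 10 adjusted over the list alone. Its leading members were Bloc1s1 (243 ± 94.6 TPM), Gpnmb, a glycoprotein of melanosomes and of phagocytes (chromosome 6, 49013480 to 49047863, 146 ± 50.2 TPM), Rab7 (71.0 ± 6.27 TPM) and Bloc1s2 (57.9 ± 3.78 TPM).

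Antigen presentation transcripts of class I were higher than those of class II. The class I list (level 4.81 ± 0.24) had 9 of 11 members above 1 TPM, with B2m followed by H2-D1 (323 ± 112 TPM), Canx (84.3 ± 6.29 TPM) and Calr (60.7 ± 18.6 TPM), and its level exceeded that of the class II list (2.61 ± 0.15) by more than the SD of either, a difference that was not tested. In the class II list 7 of 10 passed, led by the invariant chain Cd74 (51.2 ± 4.14 TPM), H2-DMb1 (32.5 ± 10.2 TPM), H2-Aa (10.2 ± 3.26 TPM) and H2-Ab1 (10.1 ± 4.13 TPM). The list of perivascular or resident macrophages (level 2.98 ± 0.63) had 6 of 11 above, or 7 adjusted over the list alone, led by Cbr2 (53.8 ± 25.4 TPM), Gas6 (32.0, 10.7 and 98.5 TPM in replicates 1, 2 and 3), Maf (38.9 ± 3.78 TPM) and the platelet and macrophage chemokine Pf4 (28.6 ± 12.6 TPM). The list of phagocytic and scavenger receptors (level 2.36 ± 0.18) had 7 of 13, led by Fcgr3 (66.2 ± 11.6 TPM), Lrp1 (18.0 ± 7.37 TPM), C3ar1 (12.8 ± 9.72 TPM) and Cd36 (8.14 ± 5.04 TPM), whose call ended without replicate 1 (limma, adjusted p = 0.0706).

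Few transcripts of the inflammatory and cell cycle lists passed. In the list of inflammatory cytokines and the NF-kB response (level 1.90 ± 0.50) 3 of 13 members stood above 1 TPM, the NF-kB inhibitor Nfkbia (287 ± 138 TPM) and the chemokines Ccl3 (28.1 ± 16.9 TPM) and Ccl4 (27.1 ± 8.42 TPM), while Cxcl10 (0.141, 13.04 and 0.0634 TPM in replicates 1, 2 and 3) did not pass. The immediate early and heat shock list (level 3.05 ± 0.53) had 6 of 11 above, led by Hspa8 (130 ± 31.5 TPM), Ier2 (75.4 ± 39.6 TPM), Dusp1 (23.0 ± 12.2 TPM) and Junb (16.1 ± 9.36 TPM). In the cell cycle list (level 1.09 ± 0.29) 1 of 10 passed, the DNA clamp Pcna at 43.1 ± 9.77 TPM, while Birc5, Rrm2 and Mcm2 did not. The interferon response list (level 4.21 ± 1.19) had 7 of 11 members above and differed between libraries more than the other functional lists, with levels of 3.34, 5.57 and 3.72 in replicates 1, 2 and 3 and 3.53 as the mean without replicate 2. Ifit3 stood at 384, 2734 and 282 TPM and Ifit1 at 53.3, 950 and 37.6 TPM in replicates 1, 2 and 3, and 8 of the 11 members were highest in replicate 2. The others were Isg15 at 11.7, 75.4 and 76.1 TPM, Ifit2 at 4.47, 9.59 and 13.3 TPM and Irf7 at 17.8, 10.1 and 10.3 TPM, the last 2 named after their values were seen. Oas1a stood at 52.3 ± 29.1 TPM. Mitochondrially encoded genes took 2.40%, 5.40% and 2.60% of the counts in replicates 1, 2 and 3. Whether reads were shared among related genes of the Ifit family was not examined, which leaves their single levels uncertain.

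**Figure D3:**
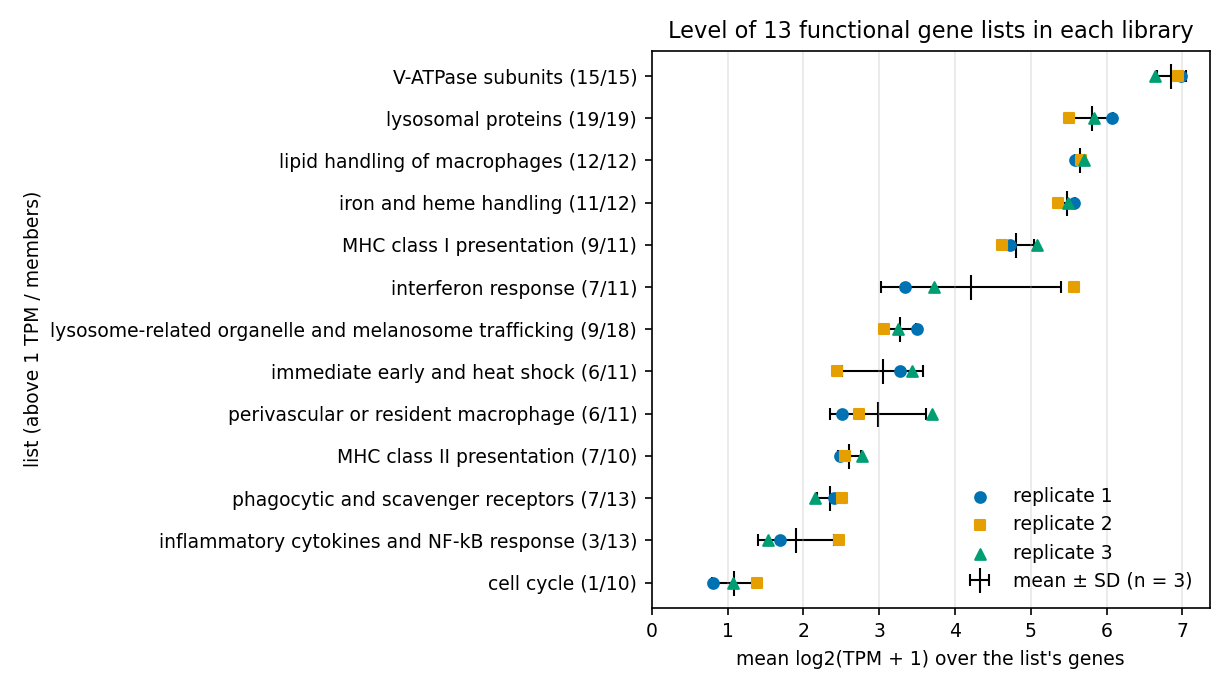
The horizontal axis gives the mean log2(TPM + 1) over the genes of each of 13 functional lists, and the numbers after each name are the members above 1 TPM in limma's test and all members. Points are the 3 libraries and black bars the mean ± SD (n = 3). V-ATPase subunits are highest at 6.86, and the interferon response list has the widest spread, from 3.34 to 5.57.

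Pearson's r across genes was 0.919 for replicates 1 and 2, 0.898 for replicates 1 and 3 and 0.892 for replicates 2 and 3, with Spearman's rho of 0.818, 0.801 and 0.788, and genes are not independent replicates. The common biological coefficient of variation was 0.934. The chi-square of the counts per degree of freedom lay between 95.3 and 148 for the 3 pairs, so no pair held the same counts within counting error. This check looks only for a library listed more than once, since PCR reads are not independent molecules. The housekeeping list stood at 6.56 ± 0.15 with 9 of 10 members above 1 TPM, or 10 adjusted over the list alone, led by Eef1a1 (877 ± 273 TPM), Rplp0 (657 ± 226 TPM) and Hprt (555 ± 291 TPM). The member that did not pass over all genes was Gapdh, at 2.78 ± 1.11 TPM, which did pass in CPM without gene length (limma, adjusted p = 0.0021), among genes counted in all 3 libraries (0.0338) and without limma's trend (0.0268). All 13 mitochondrially encoded genes passed (level 11.37 ± 0.60), led by mt-Cytb (13607 ± 8672 TPM), mt-Co1 (12497 ± 6318 TPM), mt-Co3 (11212 ± 6213 TPM) and mt-Nd1 (8764 ± 3919 TPM).

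The 10 genes with the largest spread between libraries mostly carried pseudogene symbols or provisional Gm symbols. The monocyte and macrophage gene Chil3 (chromosome 3, 106054870 to 106074880) was among them, with 0.195, 190 and 3.13 TPM in replicates 1, 2 and 3. Scp2-ps2 stood at 414, 412 and 0.632 TPM and Gm26712 at 0.621, 242 and 225 TPM. The others were Bnip3l-ps, Rps18-ps6, Rps18-ps4, Gm54988, Gm20431, a copy of Gm15501 and a gene without a symbol, ENSMUSG00000121727. Their SD of log2(TPM + 1) lay between 3.82 and 4.90.

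Transcripts of the Y chromosome were present and Xist, which is transcribed from the inactive X chromosome of females, was not counted. Of the 5 genes in this list (level 2.31 ± 0.37) 2 stood above 1 TPM. Eif2s3y (chromosome Y, 1010543 to 1028847) stood at 57.3, 38.0 and 6.50 TPM and Ddx3y (chromosome Y, 1260771 to 1286629) at 18.99, 26.2 and 11.9 TPM in replicates 1, 2 and 3. Uty stood at 0.808, 3.19 and 1.04 TPM and Kdm5d at 1.08, 0.925 and 2.70 TPM, and both passed in CPM without gene length (limma, adjusted p = 0.0045 and 0.00141). Xist (chromosome X, 102503972 to 102526860) had 0 counts in each library, which allows up to 0.163, 0.199 and 0.213 CPM in replicates 1, 2 and 3.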

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

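The macrophage list stood above the melanocyte list under every alternative that kept the macrophage list. The difference was 2.25 and 1.55 with pseudocounts of 0.1 and 5, 1.11 in CPM without gene length, 1.36 with genes counted in all 3 libraries, 1.28 with medians, 1.61 without Mitf, Kit, Sox10 and Ednrb, and 0.39 ± 0.34 with the pan-leukocyte list in its place. Low melanocyte markers weigh more at a small pseudocount and drop out under the filter. For the other moves the cause was not tested. Leaving out a library gave 1.78 to 1.95. The mean correlation between libraries (0.903) became 0.832 and 0.935 with pseudocounts of 0.1 and 5, and 0.884 to 0.913 without 1 library, over genes counted in the 2 that remained. At a level of 10 TPM, 4017 genes, 9 macrophage and 5 melanocyte markers passed, and 5039 genes reached it in every library, which the higher level itself brings. At 1 TPM, leaving out a library gave 8587 to 10027 genes, 14 to 15 macrophage markers and 9 melanocyte markers. Fewer libraries also leave less power.

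The macrophage list stood above 14 rather than 15 other lists in CPM, where the hair cell list stood higher, and with genes counted in all 3 libraries, where the B cell list kept few members. Of 206 genes examined one by one, 174 kept their call under every alternative run on them. Without replicates 1, 2 and 3, 8, 2 and 2 calls were lost and 4, 6 and 5 gained. No call above 1 TPM changed sign. Levels of 27 of 35 lists moved by more than their SD in CPM, 21 and 28 with pseudocounts of 0.1 and 5, 22 with medians, 11 with genes counted in all 3 libraries and 0 under TMM, and 2 of 34 without mitochondrially encoded genes in the total. No paired analysis was possible because the labels give 1 group, so no samples pair across groups. Lists were compared within each library. Depth limits a library to a floor between 0.163 and 0.213 CPM, and the spread between 3 libraries limits the calls: 39.9% of genes with a mean of 3 to 5 TPM passed limma's test, and Kit passed at a pseudocount of 0.1 (adjusted p = 0.0458).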

Other observations

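Apart from the shared-sequence test on ribosomal protein genes, the tests in this part were chosen after their results were seen, as were the genes of the next paragraph.

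Further inner ear transcripts outside the fixed lists stood above 1 TPM in limma's test. Slc26a4, the anion exchanger pendrin (chromosome 12, 31569826 to 31609968), stood at 37.7 ± 24.6 TPM (SD, n = 3), and Otol1, the otoconial protein otolin (chromosome 3, 69914946 to 69936041), at 9.02 ± 3.36 TPM. Cib2, a component of hair cell mechanotransduction (chromosome 9, 54452078 to 54467502), stood at 379 ± 157 TPM and the potassium channel gene Kcnj16 at 16.1 ± 9.04 TPM. The protease inhibitor Cst3 and the secreted chaperone Clu, abundant in many cells, stood at 1738 ± 138 and 1036 ± 451 TPM. Ms4a7, a macrophage gene, stood at 30.3 ± 7.00 TPM. The kappa light chain gene Igkc (chromosome 6, 70703419 to 70703950) stood at 20.8, 32.3 and 8.24 TPM in replicates 1, 2 and 3 beside Ighm at 569 ± 291 TPM, and its call ended in CPM without gene length (adjusted p = 0.0871). Ighd did not pass, at 7.59, 0.389 and 0 TPM in replicates 1, 2 and 3.

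Transcripts of hair cells, epithelium, red blood cells and melanocytes stood beside macrophage transcripts in each library. Macrophage RNA alone is argued against, since 23 of the 24 hair cell and epithelium markers stood above 1 TPM, with Gjb6 at 648 ± 166 and Ocm at 155 ± 10.4 TPM. B cell genes gave mixed results on mature B cells as the source of Ighm and Cd79a. Against them, 0 of the other 6 B cell markers passed limma's test with all libraries (0 also at an unadjusted p under 0.05). Ms4a1, Pax5, Blk and Fcrla had 0 counts in each. Cd79b did pass without replicate 3 (limma, adjusted p = 0.0127). Outside the list, Igkc passed in TPM (limma, adjusted p = 0.00106), and Ighd had 7.59 TPM in replicate 1 but did not pass. With few cells behind each library low transcripts can be missed, so mature B cells were not excluded. The 4 globin genes moved together between libraries, with log2 changes within 0.437 of each other (1.21 to 1.35 from replicate 1 to replicate 3), as red cell RNA in differing amounts would give, and this remains a candidate source of the globins. Whether the other transcripts came from material taken up by the cells, from RNA released by neighbouring cells or from several cell types among the cells lysed was not separated by any test here, because each library is a single sum. Beyond these sources of RNA no biological explanation was tested, since the design has 1 group.

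Interferon response genes differed between the libraries, with an SD of 1.19 on the log2 scale. Scaling or depth is argued against, since the SD of the housekeeping list was 0.147 in the same libraries. Differing leukocyte content cannot be told apart from other causes: the SD of the pan-leukocyte list was 0.327, with levels of 3.63, 3.69 and 4.23 in replicates 1, 2 and 3 against 3.34, 5.57 and 3.72 for the interferon list, but macrophages themselves express that list and could hide a small share of other leukocytes. The monocyte list stood at 0.33, 2.31 and 1.502 and the neutrophil list at 1.17, 3.80 and 2.32, both highest in replicate 2 like the interferon list, which leaves such cells among the open explanations. Replicate 2 also had the highest share of mitochondrially encoded counts (5.40% against 2.40% and 2.60%), and RNA quality, handling and differences between the mice stay open and were not tested.

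Gapdh, an abundant gene in most cells, stood at 2.78 ± 1.11 TPM (chromosome 6, 125138678 to 125143430). Reads assigned to rows described as this enzyme do not account for this. Of 9 rows so described, 6 had a count. They summed to 9.22 ± 2.22 TPM, against a median of 128.6 ± 24.03 TPM for the housekeeping list. Copies described otherwise were not searched for, so reads assigned to those stay open. Reads shared with other genes and then left uncounted may account for some of the low level of Gapdh. Of the 50-base words of Gapdh transcripts, 24.7% occur in other annotated genes, or 58.4% with words from protein-coding transcripts. The medians for ribosomal protein genes were 20.9% and 35.5%. Lost evenly over the words, shares of 24.7% or 58.4% would fall short of the gap between 2.78 and 128.6 TPM. How reads were spread over the words was not examined, so the size of the loss stays unknown. Some genes with larger shares stood far higher: Pgk1 (53.9% and 68.0%, 123 TPM), Rplp1 (60% and 60%, 1722 TPM) and Rps4x (41.2% and 72.2%, 398 TPM). Across 76 ribosomal protein genes, which are not independent replicates, Spearman's rho between that share and mean TPM was 0.147 (permutation p = 0.205, bootstrap interval -0.09 to 0.374) over all transcripts and -0.096 (p = 0.407, -0.313 to 0.151) over protein-coding ones, a choice added after seeing the data. A rho above -0.1 was to exclude the explanation, yet that bound was too weak. Genes with more words had a lower share (rho = -0.526) and a lower TPM (rho = -0.374), which pushes rho upward. The second interval also reaches below the bound, so shared reads stay open as a cause of some of the gap. The length implied by the count and FPKM of Gapdh was longer than the span of the gene itself (125138678 to 125143430). It was therefore too long for a transcript of this gene, which lowers its TPM. How much of the gap comes from the length used for scaling was not tested. In CPM without that length Gapdh passed limma's test against 1 CPM (adjusted p = 0.0021), a different bar from 1 TPM. Its counts were still the lowest of the housekeeping list in each library, at 153, 112 and 230 in replicates 1, 2 and 3.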
